A study of Mus musculus with 8 samples.

How the data were processed

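The 8 libraries came from vascular smooth muscle cells of the mouse aorta, 2 for each of 4 genotypes: E12 wild type, E12 knockout, E47 wild type and E47 knockout. Per the labels' protocols, frozen cells were revived in culture dishes and lysed in Trizol, and polyA-enriched libraries were made without keeping strand. The submitters' processing notes name FastQC, HISAT and featureCounts and the build GRCm38 (mm10). Versions, settings and the gene annotation are not given in the sources used here. The deposited values are whole-number counts per gene, not normalized, with 1 column per library and no pooling. Whether a count is a read or a fragment is not given in the sources used here, nor is the treatment of reads that match several places. Because strand was not kept, reads of overlapping genes on opposite strands cannot be told apart, so genes whose exons overlap another gene widely are reported as uncertain.

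The table held 55353 gene symbols or symbol-like entries, all with a name. Of these, 26 symbols had been turned into dates, 2 of which stood on 2 lines each, and these carried between 0.153% and 0.198% of a library's counts. They were kept in the library totals. Symbols were matched to GENCODE M21 (GRCm38) for positions, overlaps, GC content and transcript length, and 53256 matched. Library totals ran from 13909230 to 27517374 counts. A group total of 3 counts was taken as the limit that a count of 0 allows, which for a single library was between 0.109 and 0.216 CPM. Folds against a group with no count in either library are given as "at least", computed with 3 counts over the group. These limits cover counting error only, since reads without molecular identifiers are not independent molecules.

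Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by the filter on low counts that edgeR offers for the 4 groups, which left 13992 genes tested. Libraries were scaled by the trimmed mean of M values (TMM), a 4-group model without covariates was fitted to all 8 libraries, and contrasts were tested with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 is called past the test. The common biological coefficient of variation was 0.0598, with 4 residual degrees of freedom. CPM values use the TMM-scaled library sizes and are given as mean ± SD of the 2 libraries of a group. Changes are log2 fold changes with standard errors (SE). The contrasts were knockout against wild type for E12 and for E47, the difference of these 2 changes, and E12 wild type against E47 wild type. A separate fit used 4 profiles, each the sum of a genotype's 2 libraries, to compare both knockouts with both wild types.

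The rule for named genes, the gene lists, and the tests and alternatives were set before the data were examined, except for those tests and settings said to be chosen after. For each knockout, the rule took the 10 largest rises and the 10 largest falls among genes past the test with a mean CPM of at least 2, both knockout libraries on the same side of both wild-type libraries, and a symbol that is not a predicted model. It also took up to 4 members per gene list with the lowest p, up to 10 shared genes per direction, 5 genes per direction for the difference and for the wild types, and always Tcf3, Tcf4, Tcf12, the Id genes, the cyclin-dependent kinase (CDK) inhibitors, Acta2, Myh11, Cnn1, Tagln and the sex-specific transcripts. Other genes are said to be chosen after their values were seen. For genes with 3 counts or fewer in a group, levels are given and no fitted fold. A few genes that the rule took are not reported here.

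There were 33 gene lists with 703 symbols, 30 of which were matched by a synonym. They were E and Id proteins, contractile and modulated smooth muscle genes, matrix structural genes, matrix proteases and inhibitors, CDK inhibitors, G1/S genes, G2/M genes, p53 targets, cytokines and chemokines, interferon-stimulated genes, TGF-beta and BMP signalling, Notch signalling, Wnt signalling, cholesterol synthesis, glycolysis and hypoxia, the integrated stress and unfolded protein response, osteochondrogenic genes, immediate early genes, nuclear genes of oxidative phosphorylation, Hox genes, sex-specific transcripts, mitochondrially encoded mRNAs, replication-dependent histones, and markers of endothelial cells, adventitial fibroblasts, macrophages, lymphocytes, adipocytes, Schwann cells, striated muscle, pericytes and mesothelium. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with p adjusted over the 33 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. A list's median log2 change sets group totals under 3 counts to 3. Members are counted out of those tested. Some marker lists were mostly too low to test, with 4 of 10 adipocyte, 5 of 15 macrophage and 3 of 9 Schwann cell markers tested. For striated muscle 3 of 14 were tested and for lymphocytes 1 of 12. Members past the test were also counted with p adjusted over the list alone, and that count is given where it differs.

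The libraries of a genotype were compared by a chi-square test over genes with at least 20 counts. It gave 14.2 per degree of freedom for the E12 wild type, 5.16 for the E12 knockout, 4.77 for the E47 wild type and 5.04 for the E47 knockout, so no pair was a library counted again. The E12 wild-type pair varied most. Because the 4-group fit shares 1 estimate of the spread, p-values that involve this group may be too small. Fitted on the compared groups alone, 5880 of 6490 E12 calls and 7640 of 7728 E47 calls were kept. The model was tested on simulated counts for the 13992 genes. For the E12 comparison it called 34, 40, 49 and 49 of 50 genes changed 1.5, 2, 4 and 8-fold, and 9 unchanged genes. For the difference of changes it called 26, 36, 45 and 48 of 50, and 7 unchanged genes. For the summed profiles it called 38, 45, 49 and 49 of 50, and 12 unchanged genes. That simulation also used the 13992 genes, while the fit of summed profiles tested 14704, and it set the spread between genotypes to that between libraries of a genotype, so it does not give the power at the spread of the data. Alternatives were DESeq2 1.42.0, RLE size factors, other filters on low counts, a fit of the compared groups alone, leaving out each library in turn, and for the lists the other tests. Median changes per chromosome were taken over tested genes, minus the median of all genes, with bootstrap errors, and set against 1000 random assignments of genes to chromosomes.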

Results

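Gene expression was measured by mRNA sequencing in vascular smooth muscle cells cultured from the mouse aorta. The cells were wild type or knockout for E12, or wild type or knockout for E47. E12 and E47 are isoforms of the basic helix-loop-helix transcription factor E2A, encoded by Tcf3, that differ in the exon for the DNA-binding domain. Id proteins bind E proteins and keep them from DNA, and the series concerns E-protein activity and cell proliferation. Each genotype had 2 libraries from separate extractions, 8 in all. Total counts were 15628499 and 13909230 in the E12 wild type, 19532369 and 16086544 in the E12 knockout, 14912823 and 27517374 in the E47 wild type, and 18394466 and 14452545 in the E47 knockout. The labels do not say whether the libraries of a genotype came from separate cultures or animals. The p-values therefore measure only the spread between extractions, which may be technical, and each genotype was 1 cell population as far as the labels tell.

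Tcf3, the gene that encodes both targeted isoforms, was higher in each knockout than in its wild type. It was at 109 and 108 CPM in the E12 wild-type libraries, 145 and 143 CPM in the E12 knockout, 94.6 and 93.7 CPM in the E47 wild type, and 128 and 128 CPM in the E47 knockout. The log2 change was 0.41 (SE 0.0634, adjusted p = 8.6e-05) in E12 and 0.44 (SE 0.0636, adjusted p = 3.4e-05) in E47. The test of the difference between the changes gave -0.03 (SE 0.0897, adjusted p = 0.80). In GRCm38, Tcf3 lies on chromosome 10 from 80409514 to 80433647, on the minus strand. It has 2 mutually exclusive coding exons. Of its 12 annotated coding transcripts, 7 use the exon from 80410398 to 80410624 (227 bp) and 4 that from 80412827 to 80413062 (236 bp). None uses both, and not every transcript uses either. A count per gene does not separate these exons, so it does not check which isoform a library had lost.

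The other E and Id protein genes moved in different directions. Tcf4, which encodes the E protein E2-2, rose in the E12 knockout from 19.1 ± 0.621 to 47.5 ± 1.09 CPM (log2 change 1.32, SE 0.0822, adjusted p = 6.9e-09). In the E47 lines it was far higher in both genotypes and fell from 98.8 ± 1.80 to 84.6 ± 4.25 CPM (-0.23, adjusted p = 0.012). Tcf12, which encodes HEB, was at 100.1 and 101 CPM in the E12 lines and at 103 and 94.0 CPM in the E47 lines, with no change past the test. Id1 fell in the E12 knockout (-0.69, SE 0.0781) and rose in the E47 knockout (0.31, SE 0.0782). Id3 fell in the E12 knockout from 203 ± 12.8 to 133 ± 14.5 CPM (-0.61, adjusted p = 8.0e-05) and was at 258 ± 16.8 and 261 ± 29.9 CPM in the E47 lines. Id2 fell in both (-0.30 and -0.31), and Id4 fell in the E47 knockout (-0.80). The 7 genes thus held 2 higher and 3 lower in each knockout, and camera called the list in neither (adjusted p = 0.99 in E12 and 0.67 in E47). In E12 the list's median was -0.18 while the test leaned up.

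Several of these smaller changes rested on single libraries. Leaving out 1 library ended the E47 calls of Tcf4, Id1 and Id2 and the E12 call of Id2. Tcf4 was at -0.16 (adjusted p = 0.13) without the first knockout library and at -0.21 (0.086) without the second wild-type library. Id1 was at 0.22 (0.067) without the second knockout library and at 0.26 (0.055) without the second wild-type library. Id2 was at -0.21 (0.20) without the first knockout library and at -0.26 (0.11) without the first wild-type library. In E12, Id2 was at -0.12 (0.45) without the second knockout library and at -0.23 (0.17) without the first wild-type library, and also missed the threshold without either E47 knockout library (-0.29, adjusted p = 0.054 in each case), with DESeq2 (-0.30, adjusted p = 0.056) and in a fit of the E12 groups alone (-0.30, adjusted p = 0.068).

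**Figure D1:**
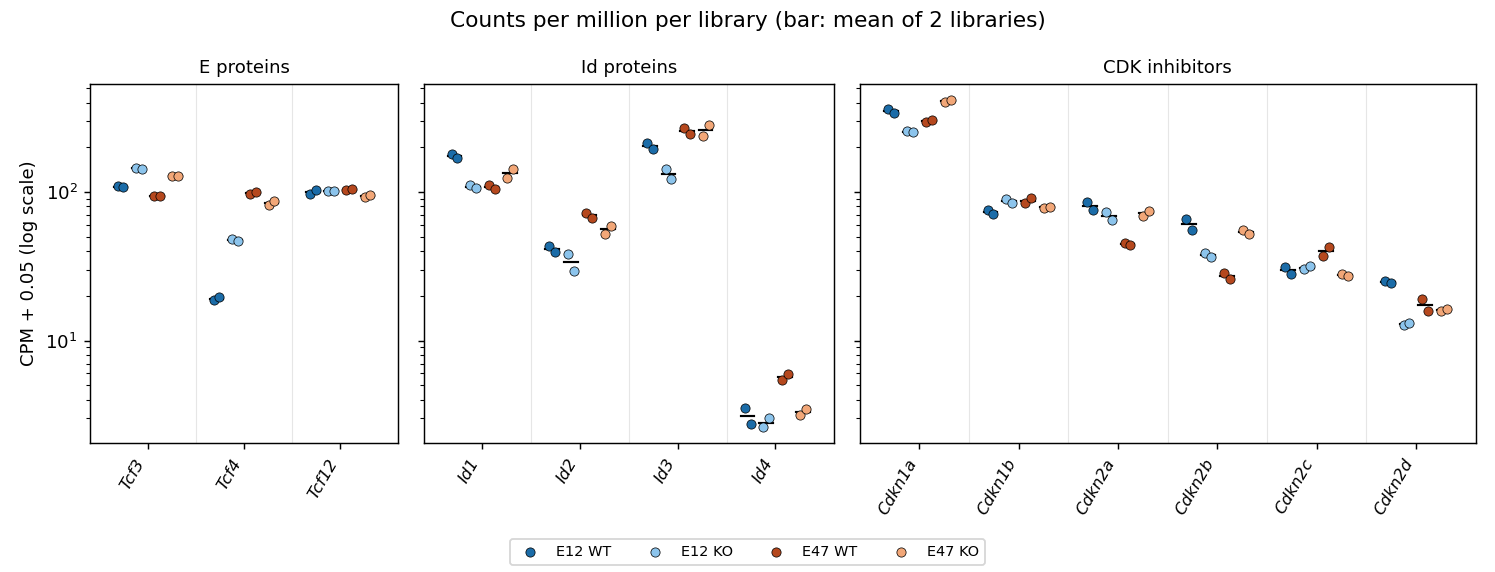
CPM per library, plus 0.05 and on a log scale, of the E protein, Id protein and CDK inhibitor genes in the 4 genotypes, with points for the 2 libraries and bars for their mean. Tcf3 stood at 144 and 128 CPM in the knockouts against 108 and 94.2 CPM in their wild types, and Tcf4 at 19.1 CPM in the E12 wild type against 98.8 CPM in the E47 wild type.

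Across all tested genes the 4 genotypes formed 4 separate profiles. The libraries of a genotype correlated at r = 0.992 to 0.995 across genes, with root mean square log2 differences of 0.280 to 0.350. Genotype means differed more, by 0.747 between the E12 wild type and the E47 knockout (r = 0.962), 0.852 between E12 wild type and E12 knockout, and 0.983 between E47 wild type and E47 knockout. The wild types differed from each other by 1.14 (r = 0.913). The E12 knockout differed from the E47 wild type by 1.33, the largest of these distances, and from the E47 knockout by 0.977. Genes are not independent replicates, so these correlations describe profiles. The first principal component carried 56.4% of the variance and ran from the E47 wild type to the E12 knockout, with the other genotypes between them. The next components carried 23.0% and 14.9%.

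**Figure D2:**
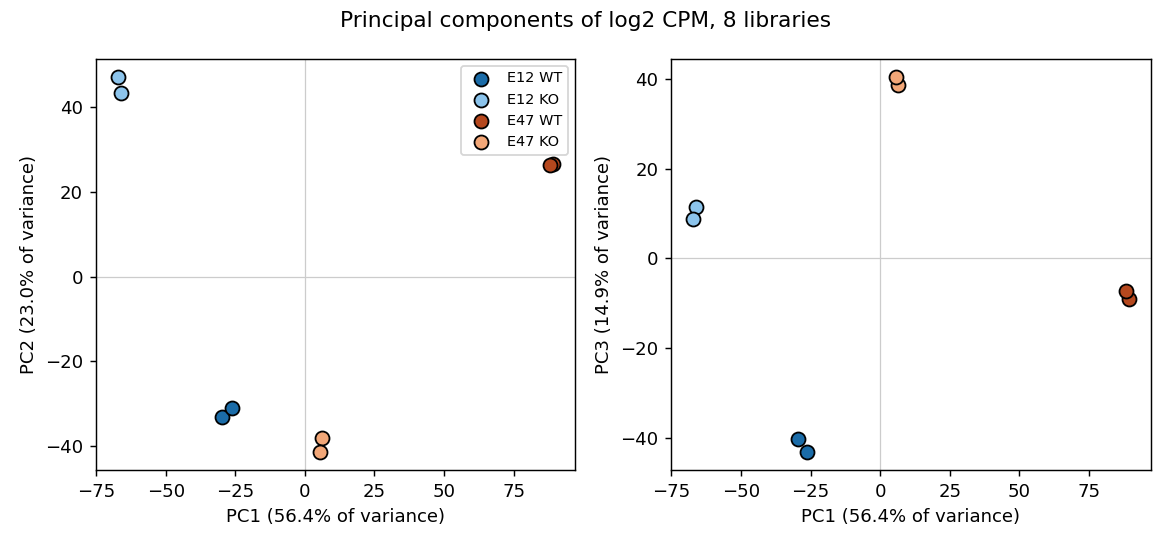
Principal components of log2 CPM for the 8 libraries, with the later components each against the first (percent of variance on the axes). The libraries of a genotype sat together. On the first component the E47 wild type lay at 89.3 and 88.2, the E12 wild type at -29.7 and -26.3, and the E12 knockout at -66.0 and -67.3.

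The first comparison asked which transcripts differ when E12 is lost. Matrix structural genes, TGF-beta and BMP pathway genes and Wnt pathway genes were lower in the E12 knockout as lists. These calls did not hold with an estimated correlation (adjusted p = 0.59, 0.59 and 0.47). Col2a1, which encodes the type II collagen of cartilage and is on the osteochondrogenic list, which was not called (adjusted p = 0.087), fell from 205 ± 21.4 to 1.69 ± 0.00525 CPM (mean ± SD, n = 2 libraries, log2 change -6.91, SE 0.12, adjusted p = 2.2e-14). Eng, a TGF-beta co-receptor, fell from 62.8 ± 6.38 to 4.39 ± 0.0818 CPM (-3.83, SE 0.107, adjusted p = 2.0e-12). Sfrp1, a secreted Wnt antagonist, fell from 27.7 ± 0.364 to 1.93 ± 0.0707 CPM (-3.84, SE 0.115, adjusted p = 3.3e-12). Of the 13992 genes, 3064 rose and 3426 fell, of which 536 and 1135 did so more than 2-fold. Fitted without the E47 wild-type libraries, a setting chosen after seeing the data, 2927 rose and 3325 fell.

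The genes with the largest rises in the E12 knockout came from several families. Myo5c, an unconventional myosin, rose from 0.283 ± 0.129 to 30.3 ± 0.306 CPM (log2 change 6.74, SE 0.221, adjusted p = 6.1e-12). Kit, the stem cell factor receptor, rose from 0.714 ± 0.164 to 23.3 ± 1.47 CPM (4.99, SE 0.237). Bche, which encodes butyrylcholinesterase, rose by 5.54, the keratin gene Krt14 by 5.58, and Gatm, the first enzyme of creatine synthesis, by 4.47 on the log2 scale. Eps8l2 went from 3 counts in the wild type to 17.9 ± 1.53 CPM, and 32.2% of its exon length overlaps another gene. Xlr3b (chromosome X, 73192207 to 73202930) had no count in the wild type and was at 9.62 ± 0.0808 CPM in the knockout, at least 93.0-fold higher, and Rps4l was at least 59.6-fold higher. Xlr3b belongs to a family of near copies and Rps4l resembles a processed copy of a ribosomal protein gene, so both counts are uncertain. Pcdhga11 rose by 6.86 and Pcdhga4 by 4.49, but these protocadherin genes share exons with their neighbours on chromosome 18 over 73.6% and 66.8% of their length, so their counts are uncertain too.

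The 10 largest falls in the E12 knockout included the transcription factor genes Gata4, Nkx2-1 and Hoxa10 and the matrix genes Lama2 and Comp. Lama2, a laminin chain of basement membranes, fell from 75.7 ± 23.6 to 0.536 ± 0.00685 CPM (log2 change -7.12, SE 0.275, adjusted p = 3.5e-11). Comp, a cartilage matrix protein gene, fell from 16.6 ± 1.37 to 0.0966 ± 0.137 CPM (-7.18, SE 0.35). Epb41l3 (chromosome 17, 69075683 to 69289989), a membrane cytoskeleton linker gene, was at 50.2 ± 3.07 CPM in the wild type and had 3 counts in the knockout. Gata4, the carboxypeptidase-like gene Cpxm2 and Syndig1 had no count in the knockout and were at least 76.3-fold, 88.7-fold and 85.7-fold lower than in the wild type. Hoxa10 went from 12.7 ± 1.41 CPM to 3 counts over both libraries, Nkx2-1 from 9.42 ± 1.68 CPM to 1 count, Arfgef3 from 5.63 ± 2.72 CPM to 1 count, and Mal2 from 4.52 ± 0.066 CPM to 1 count.

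Camera called 5 of the 33 lists in the E12 knockout, and none held its call when the correlation between genes was estimated. Without the second E12 knockout library 8 lists were called, the added ones being the stress response, osteochondrogenic and mesothelial lists (adjusted p = 0.038 each). Of 30 matrix structural genes 18 fell and 2 rose (median -0.67, adjusted p = 0.00051, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone, 19 fell. Thbs2, a matricellular protein gene, fell by 5.50, Loxl1, an elastin cross-linking enzyme gene, by 1.29 and Col6a2 by 1.04 on the log2 scale, while Ogn rose by 1.15. Of 31 TGF-beta and BMP pathway genes 17 fell and 6 rose (median -0.36, adjusted p = 0.0022, and adjusted p = 0.59 with an estimated correlation). Bmp6 fell from 51.0 ± 5.01 to 3.62 ± 0.0654 CPM, and Smad6, an inhibitor of BMP signalling, from 222 ± 3.42 to 50.4 ± 1.55 CPM. Of 24 Wnt pathway genes 12 fell and 3 rose (median -0.70, adjusted p = 0.011, and adjusted p = 0.47 with an estimated correlation), and 13 fell adjusted over the list alone. Ccn5 fell by 3.25 and Sfrp4 by 1.94, and Wif1 went from 4.32 ± 0.93 CPM to 3 counts. Ccn5 is a Wnt-induced gene, whereas Sfrp1, Sfrp4 and Wif1 encode Wnt antagonists.

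In the same comparison, 12 of 13 mitochondrially encoded mRNAs fell and none rose (median -0.82, adjusted p = 0.0020, and adjusted p = 0.60 with an estimated correlation). The count of 0 rises is from edgeR, and adjusted over the list alone it was also 0. mt-Co2 fell from 211 ± 34.3 to 87.5 ± 10.4 CPM and mt-Nd4 from 877 ± 164 to 445 ± 18.0 CPM. The share of all counts on genes with an mt- symbol, whether mRNA or not, was 1.11% and 1.38% in the E12 wild-type libraries. It was 0.892% and 0.798% in the knockout. Only 4 of the 10 adipocyte markers were tested, 2 of them with a group at 3 counts or fewer. Of these 4, 3 rose and none fell (median 1.07, adjusted p = 0.0080, and adjusted p = 0.47 with an estimated correlation), and all 4 rose adjusted over the list alone. Pparg, a regulator of fat cell differentiation, rose from 9.90 ± 0.454 to 27.4 ± 0.503 CPM, Fabp4 went from 2 counts to 2.25 ± 0.0326 CPM, and Cebpa rose by 0.68. The Cebpa call ended without the first knockout library (0.65, adjusted p = 0.083), without the first wild-type library (0.60, 0.11) and with DESeq2 (0.67, 0.11).

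Contractile and cell cycle genes were divided in the E12 knockout. Of 26 contractile genes 12 fell and 7 rose (median -0.25, adjusted p = 0.14). Acta2, smooth muscle actin, fell from 1955 ± 34.8 to 1639 ± 16.9 CPM (-0.25, SE 0.0644), Myh11, smooth muscle myosin, from 7.45 ± 1.95 to 2.43 ± 0.563 CPM (-1.62), Cnn1, calponin, from 7.34 ± 0.544 to 2.31 ± 0.0525 CPM (-1.67), and Myocd, a coactivator of contractile genes, from 11.3 ± 1.41 to 1.66 ± 0.634 CPM (-2.79). Tagln was at 1.71 and 1.04 CPM, a low and uncertain count, since 67.9% of its exon length overlaps other genes. Modulated smooth muscle genes were split 8 up and 8 down of 20 (9 down adjusted over the list alone), with Vcan up by 1.39 and Tnfrsf11b at -2.76. Among CDK inhibitors, Cdkn2d (-0.95), Cdkn2b (-0.68), Cdkn1a (-0.46) and Cdkn2a (-0.21) fell and Cdkn1b rose (0.25), 4 lower and 1 higher of 6 (camera adjusted p = 0.27). Of 45 G1/S genes 12 rose and 7 fell (adjusted p = 0.34), and of 56 G2/M genes 16 rose and 9 fell (adjusted p = 0.31, with 15 up adjusted over the list alone). Mcm6, a replication helicase subunit, rose by 0.69, and Gtse1 fell by 0.77. The Cdkn2a call was marginal (adjusted p = 0.049) and ended without the first wild-type library (-0.13, adjusted p = 0.31), the second knockout library (-0.12, 0.37), either E47 wild-type library (-0.21, 0.063) or either E47 knockout library (-0.21, 0.067 and 0.068), with DESeq2 (-0.22, adjusted p = 0.094) and in a fit of the E12 groups alone (-0.21, adjusted p = 0.081). The Cdkn1b call ended without the first knockout library (0.21, 0.091) and without the second wild-type library (0.20, 0.071).

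The remaining lists were not called in the E12 knockout. Members that fell and rose were 11 and 5 of 19 matrix proteases and inhibitors (adjusted p = 0.27), 13 and 5 of 25 p53 targets (0.18), 9 and 6 of 20 cytokines and chemokines (0.58), 4 and 7 of 28 interferon-stimulated genes (0.77), 7 and 3 of 15 Notch pathway genes (0.12), 5 and 7 of 24 cholesterol synthesis genes (0.89), 6 and 14 of 25 glycolysis and hypoxia genes (0.11), 15 and 6 of 25 stress response genes (0.058), 8 and 3 of 13 osteochondrogenic genes (0.087), 8 and 5 of 20 immediate early genes (0.50), 8 and 5 of 29 nuclear genes of oxidative phosphorylation (0.99), 12 and 7 of 23 Hox genes (0.058), 1 and 4 of 17 histones (0.33), and 1 and 3 of 5 sex-specific transcripts (0.27). Ptgs2, the inducible cyclooxygenase, fell from 399 ± 24.2 to 82.5 ± 0.289 CPM, Dusp1, an immediate early phosphatase gene, fell by 1.23, and Hoxb9 fell by 5.65 on the log2 scale. Hspa5, an endoplasmic reticulum chaperone gene, fell from 1633 ± 22.3 to 1021 ± 31.5 CPM, Notch3 fell by 1.55, and Eno1, a glycolytic enzyme gene, rose from 868 ± 47.2 to 1365 ± 25.2 CPM. Mmp2 rose by 1.74 and Gdf15, a p53 target, fell by 1.24. Adjusted over the list alone, 6 proteases and inhibitors, 6 p53 targets, 15 glycolysis and hypoxia genes and 2 histones rose, and 10 cytokines, 8 Notch pathway genes and 0 histones fell. For modulated, interferon, cholesterol, oxidative phosphorylation, adventitial and Schwann cell genes, the median, mean and tests differed in sign.

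Markers of other cell types also differed in the E12 lines. Mesothelial markers fell in 6 of 8 cases and rose in 2 (median -0.94, adjusted p = 0.058). Krt19 fell from 387 ± 32.2 to 171 ± 10.4 CPM, and Wt1 fell from 11.6 ± 0.57 to 2.00 ± 0.449 CPM. Of 12 endothelial markers 3 fell (median -1.36, adjusted p = 0.087), and the list was called without the first or the second E47 knockout library (adjusted p = 0.046 in each case). Pecam1 was at 2.05 ± 0.278 and 0.458 ± 0.0327 CPM. Members that fell and rose were 4 and 6 of 14 adventitial fibroblast markers (adjusted p = 0.83), 4 and 2 of 9 pericyte markers (0.25, with 5 down adjusted over the list alone), 3 and 2 of 5 macrophage markers (0.99), 1 and 1 of 3 Schwann cell markers (0.99) and 1 and 1 of 3 striated muscle markers (0.99), and the 1 lymphocyte marker tested was not past the test (0.83).

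The second comparison asked which transcripts differ when E47 is lost. Contractile, G2/M and endothelial marker genes were lower in the E47 knockout than in the E47 wild type, and cytokine genes and nuclear genes of oxidative phosphorylation were higher. None of these 5 list calls held with an estimated correlation (adjusted p = 0.16, 0.38, 0.11, 0.17 and 0.47). Against the E47 wild type, the E12 wild type was also lower in contractile and endothelial genes (medians -0.72 and -6.44). It was also higher in cytokine and oxidative phosphorylation genes (1.10 and 0.33). Its G2/M genes, unlike those of the E47 knockout, were higher (0.37). Myh11 fell from 98.3 ± 1.74 to 6.93 ± 0.719 CPM (log2 change -3.82, SE 0.124, adjusted p = 2.2e-12) and Cnn1 from 103.6 ± 4.18 to 19.8 ± 1.71 CPM (-2.38, SE 0.0825, adjusted p = 4.6e-12). Pecam1, an endothelial adhesion molecule gene (chromosome 11, 106654217 to 106750628), fell from 203 ± 12.1 to 0.554 ± 0.0262 CPM (-8.49, SE 0.135, adjusted p = 4.9e-15). Il33, which encodes an alarmin cytokine, rose from 0.654 ± 0.0128 to 118 ± 2.48 CPM (7.47, SE 0.129, adjusted p = 4.9e-15). Of 13992 genes, 3875 rose and 3853 fell, of which 1077 and 1006 did so more than 2-fold. With the E12 wild type as the control in place of the E47 wild type, a setting chosen after seeing the data, 2598 genes were higher and 2736 lower in the E47 knockout.

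Besides Il33, the largest rises in the E47 knockout included Cdh1 and Ppp2r2b. Cdh1, E-cadherin, rose from 0.332 ± 0.139 to 36.4 ± 2.96 CPM (log2 change 6.87, SE 0.216, adjusted p = 1.7e-12), and Ppp2r2b, a phosphatase regulatory subunit gene, from 0.361 ± 0.207 to 41.4 ± 0.829 CPM (6.66, SE 0.169). Sparcl1 (chromosome 5, 104079111 to 104113733) had counts in the E47 knockout alone, at 4.04 ± 0.631 CPM, at least 52.5-fold higher than in the E47 wild type. Rtn4rl2, the chemokine gene Ccl7, the glutamate receptor gene Grin2a and the fatty acid receptor gene Ffar4 had 1 count each in the E47 wild type and were at 12.6 ± 2.93, 6.83 ± 0.861, 6.82 ± 0.367 and 4.08 ± 0.847 CPM in the knockout. Hopx had 3 counts in the wild type and was at 9.25 ± 1.39 CPM in the knockout, with 27.2% of its exon length overlapping Hopxos.

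The 10 largest falls in the E47 knockout included the endothelial markers Cdh5, Pecam1 and Emcn. Tal1, a haematopoietic and endothelial partner of E proteins (chromosome 4, 115056426 to 115071755), was at 43.7 ± 0.213 CPM in the E47 wild type and had no count in the knockout, at least 498-fold lower. Adcy4 was at least 332-fold lower, Hoxd8 at least 199-fold, Prom1 at least 110-fold, Sox7 at least 90.4-fold, Isl1 at least 78.0-fold and Clec1a at least 44.6-fold lower. Cdh5, VE-cadherin, fell from 170.5 ± 5.40 to 0.301 ± 0.236 CPM (-9.02, SE 0.169), and Emcn, endomucin, from 177 ± 27.5 to 0.572 ± 0.515 CPM (-8.36, SE 0.222). All 12 tested endothelial markers fell (median -6.73, camera adjusted p = 5.1e-08, and adjusted p = 0.11 with an estimated correlation). Both E12 groups were also low in these genes, with Pecam1 at 2.05 and 0.458 CPM and Vwf at 0.864 and 0.470 CPM against 63.3 ± 1.31 CPM in the E47 wild type.

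Contractile genes fell in the E47 knockout beside these endothelial markers. Of 26 contractile genes 19 fell and 2 rose (median -0.80, adjusted p = 2.1e-06, and adjusted p = 0.16 with an estimated correlation), and 20 fell and 3 rose adjusted over the list alone. Mylk, myosin light chain kinase, fell from 169.6 ± 4.54 to 23.0 ± 0.135 CPM, Myl9 from 215 ± 3.75 to 67.0 ± 3.46 CPM, and Acta2 from 3569 ± 180.2 to 2109.5 ± 13.9 CPM (-0.76, SE 0.0646). Myocd rose from 4.90 ± 0.241 to 12.2 ± 0.912 CPM (SE 0.163 on the log2 scale, adjusted p = 8.7e-06). Tagln fell by 1.57 on the log2 scale, with the same overlap as before. Of 20 modulated smooth muscle genes 13 rose and 5 fell (median 0.96, adjusted p = 0.0095, and adjusted p = 0.34 with an estimated correlation). Dcn, a small proteoglycan gene, rose from 2.05 ± 0.141 to 94.7 ± 6.08 CPM, Vcam1 from 143 ± 5.91 to 438 ± 13.8 CPM and Lgals3 by 2.39. Adventitial fibroblast markers rose in 10 of 14 cases and fell in 3 (median 2.22, adjusted p = 0.0062, and adjusted p = 0.23 with an estimated correlation), with Col14a1 up by 2.22, Cd55 up by 3.20 and Cd34 at -2.36. Mesothelial markers rose in 6 of 8 cases and fell in 2 (median 3.12, adjusted p = 0.0076, and adjusted p = 0.23 with an estimated correlation). Msln, mesothelin, rose from 1.09 ± 0.118 to 44.1 ± 2.29 CPM, and Krt18 fell from 117 ± 7.86 to 1.18 ± 0.126 CPM.

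**Figure D3:**
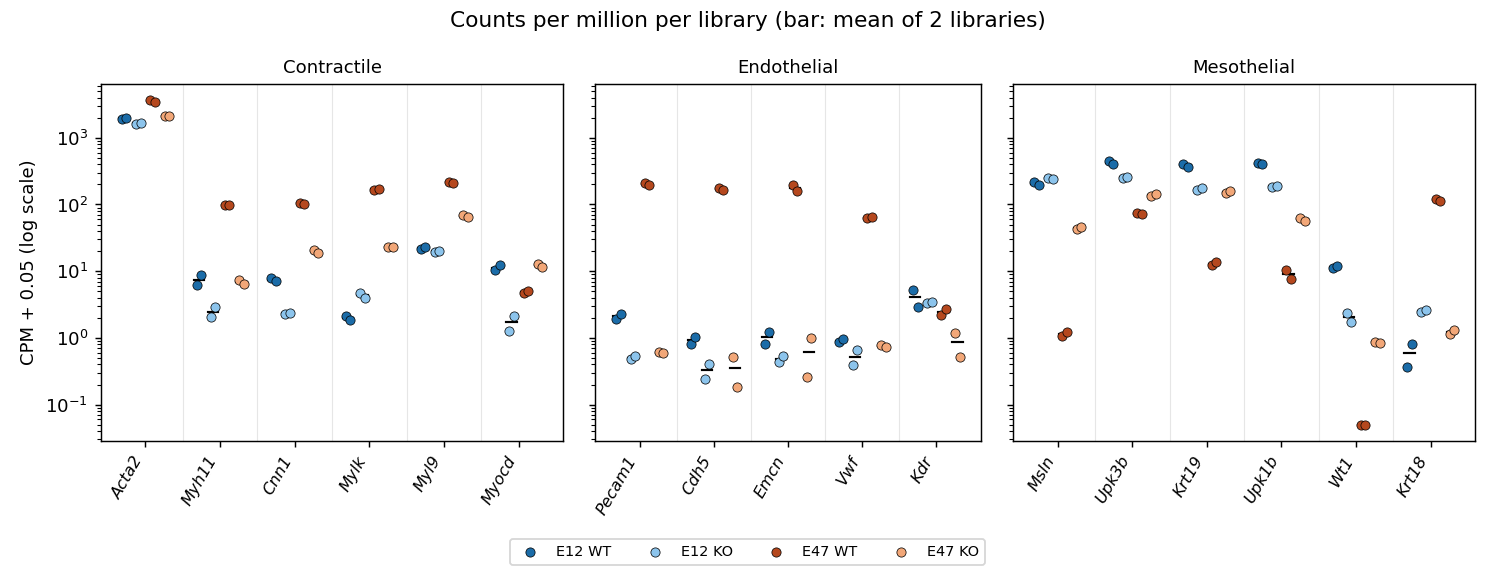
CPM per library, plus 0.05 and on a log scale, of contractile, endothelial and mesothelial genes in the 4 genotypes, with points for the 2 libraries and bars for their mean. The E47 wild type was highest in Myh11 (98.3 CPM), Pecam1 (203 CPM) and Krt18 (117 CPM), while Kdr, chosen after its values were seen, stood at 4.01 CPM in the E12 wild type and 2.40 CPM in the E47 wild type.

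G2/M genes and replication-dependent histones were lower in the E47 knockout, and G1/S genes were not called as a list. Of 56 G2/M genes 40 fell and 1 rose (median -0.35, adjusted p = 2.1e-06, and adjusted p = 0.38 with an estimated correlation), and 41 fell adjusted over the list alone. Mki67, a marker of cycling cells, fell from 110.0 ± 7.33 to 42.3 ± 0.455 CPM (-1.37, SE 0.168), Cenpe from 47.4 ± 5.32 to 22.3 ± 0.466 CPM and Ccna2, cyclin A2, by 0.66. Of 45 G1/S genes 19 fell and 6 rose (median -0.16, adjusted p = 0.068, and adjusted p = 0.60 with an estimated correlation), and this list was called without the first E47 knockout library (adjusted p = 0.046). Clspn fell by 1.32 and Mcm7 rose by 0.53. Of 17 replication-dependent histones 11 fell and none rose (median -1.02, adjusted p = 0.0049, and adjusted p = 0.27 with an estimated correlation), and 13 fell adjusted over the list alone. These mRNAs lack polyA tails in dividing cells, and H1f4 was at 11.6 ± 1.33 and 3.91 ± 0.798 CPM. The CDK inhibitors Cdkn2b (from 27.0 ± 1.84 to 53.7 ± 2.38 CPM), Cdkn2a (0.69, SE 0.0856) and Cdkn1a (0.44, SE 0.0644) rose and Cdkn2c fell (-0.53), 3 higher and 1 lower of 6 (camera adjusted p = 0.55). Of 25 p53 targets 13 rose and 5 fell (adjusted p = 0.20), with Btg2 up by 1.16.

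Cytokine and immediate early genes rose in the E47 knockout. Of 20 cytokine and chemokine genes 14 rose and 3 fell (median 1.03, adjusted p = 0.00066, and adjusted p = 0.17 with an estimated correlation). Ptgs2 rose from 87.9 ± 6.04 to 248 ± 17.3 CPM (1.49, SE 0.0775), while Icam1, an adhesion molecule gene of activated endothelium, fell from 91.1 ± 8.70 to 2.24 ± 0.521 CPM and Csf1 fell from 2014 ± 3.07 to 1059 ± 26.6 CPM. Of 20 immediate early genes 12 rose and 2 fell (median 0.52, adjusted p = 0.012, and adjusted p = 0.47 with an estimated correlation). Egr1 rose from 209 ± 17.4 to 581 ± 25.5 CPM and Dusp1 from 145 to 291 CPM, while Klf2 and Maff fell by 2.58 and 1.45. Of 29 nuclear genes of oxidative phosphorylation 24 rose and none fell (median 0.38, adjusted p = 0.00020, and adjusted p = 0.47 with an estimated correlation), and 25 rose adjusted over the list alone. Ndufv1 rose from 51.2 ± 0.188 to 81.6 ± 0.711 CPM and Uqcrfs1 by 0.71. Mitochondrially encoded mRNAs went the other way, with 12 of 13 lower and none higher (median -0.64, adjusted p = 0.00066, and adjusted p = 0.47 with an estimated correlation), and all 13 lower adjusted over the list alone. mt-Nd5 fell from 3066 ± 281 to 1008 ± 137 CPM. The share of counts on genes with an mt- symbol, whether mRNA or not, was 2.13% and 1.73% in the E47 wild-type libraries. It was 1.18% and 1.11% in the knockout.

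TGF-beta and BMP pathway, osteochondrogenic, Hox and stress response genes were also lower in the E47 knockout. In the E12 wild type against the E47 wild type, the medians of these lists were -0.44, -1.49, -0.57 and 0.07. Of 31 TGF-beta and BMP pathway genes 18 fell and 7 rose (median -0.52, adjusted p = 0.0079, and adjusted p = 0.47 with an estimated correlation), and 19 fell adjusted over the list alone. Bmp6 fell from 365 ± 12.2 to 13.8 ± 1.65 CPM (-4.71, SE 0.0973) and Bmp4 from 829 ± 8.02 to 245 ± 13.6 CPM. Of 13 osteochondrogenic genes 9 fell and 1 rose (median -1.05, adjusted p = 0.0041, and adjusted p = 0.34 with an estimated correlation), with Col11a1 at -1.60 and Sox9 at -0.61. Of 23 Hox genes 15 fell and 2 rose (median -0.68, adjusted p = 0.00020, and adjusted p = 0.34 with an estimated correlation), and 16 fell adjusted over the list alone. Hoxa9 fell from 39.7 ± 1.80 to 1.48 ± 0.552 CPM and Hoxa5 from 103 ± 6.69 to 25.4 ± 2.26 CPM. Of 25 stress response genes 16 fell and 3 rose (median -0.19, adjusted p = 0.010, and adjusted p = 0.47 with an estimated correlation). Mthfd2 fell by 0.81 and Nupr1 by 0.59, while Psat1, an enzyme of serine synthesis, rose by 0.72.

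The remaining lists were not called in the E47 knockout. Members that fell and rose were 15 and 10 of 30 matrix structural genes (adjusted p = 0.16), 6 and 9 of 19 matrix proteases and inhibitors (0.38), 8 and 7 of 28 interferon-stimulated genes (0.85), 5 and 4 of 15 Notch pathway genes (0.56, with 6 down adjusted over the list alone), 6 and 12 of 24 Wnt pathway genes (0.56), 6 and 5 of 24 cholesterol synthesis genes (0.65), 7 and 12 of 25 glycolysis and hypoxia genes (0.28, with 13 up adjusted over the list alone), 4 and 1 of 5 sex-specific transcripts (0.16), 4 and 2 of 9 pericyte markers (0.34, with 6 down adjusted over the list alone), 3 and 1 of 5 macrophage markers (0.44), 1 and 1 of 4 adipocyte markers (0.77), 0 and 2 of 3 Schwann cell markers (0.20), and 2 and 0 of 3 striated muscle markers (0.11). The 1 lymphocyte marker tested, Ebf1, fell from 3.83 ± 0.652 to 1.62 ± 0.163 CPM (camera adjusted p = 0.31). Fbln5, an elastic fibre gene, fell from 7368 ± 74.2 to 1637 ± 54.9 CPM and Eln, elastin, from 2500.3 ± 87.3 to 677 ± 0.0742 CPM. Fzd4, a Wnt receptor gene, fell by 3.42, Wnt4 rose by 4.71, Notch1 fell by 1.79, Adm, adrenomedullin, fell by 3.82 and Bst2 fell by 1.88. The Wnt list had a median of 0.60 and camera leaned up, while fry gave a fall (adjusted p = 0.0020). The median, mean and tests also differed in sign for cholesterol, adipocyte and pericyte genes.

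**Figure D4:**
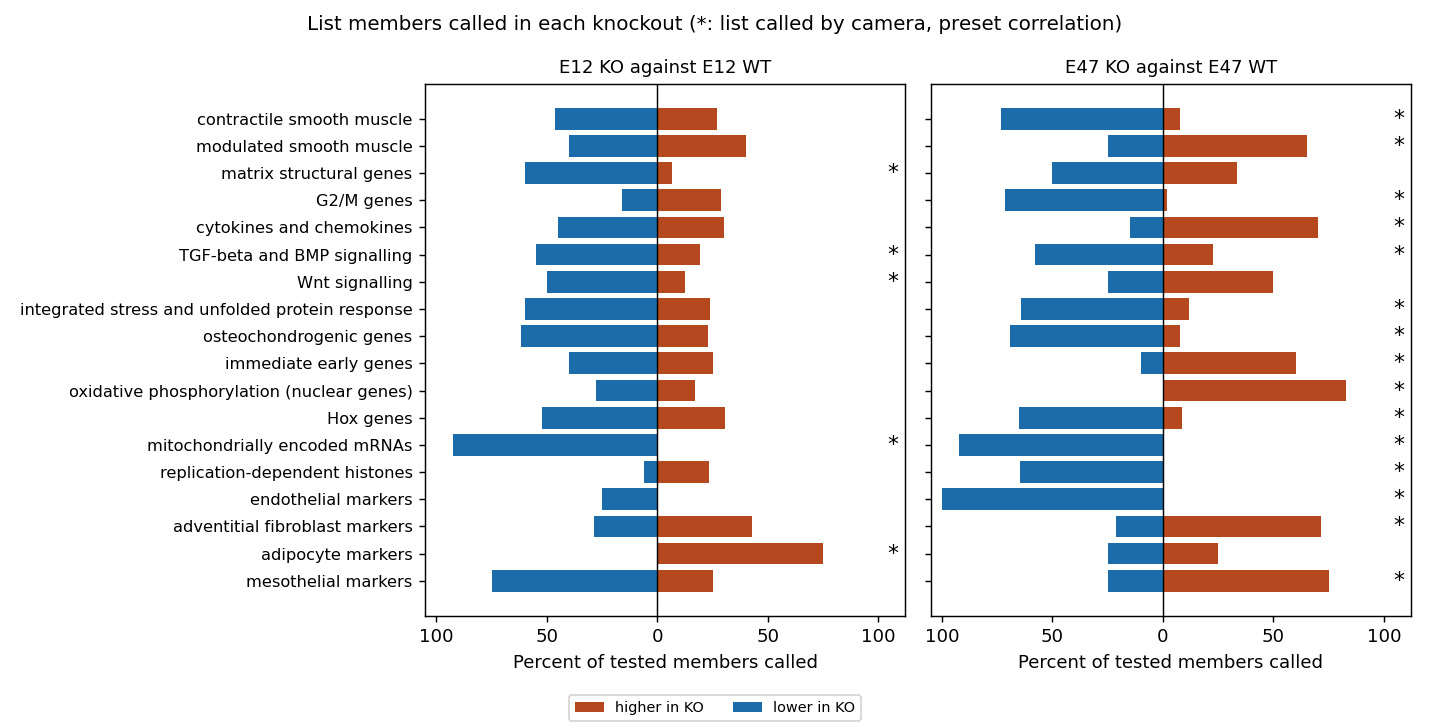
Percent of the tested members of each gene list that were higher (right) or lower (left) in the E12 knockout and in the E47 knockout, for lists that camera called in either comparison at the preset correlation (asterisk where called). All 12 endothelial markers and 40 of 56 G2/M genes were lower in the E47 knockout, and 18 of 30 matrix structural genes were lower in the E12 knockout.

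Sex-specific transcripts were measured in every library to compare the cell populations. The Y-linked gene Ddx3y was at 107 ± 0.90 and 85.0 ± 0.00893 CPM in the E12 wild type and knockout, and at 145 ± 12.1 and 96.7 ± 9.42 CPM in the E47 wild type and knockout. Kdm5d, Eif2s3y and Uty were counted in all 4 genotypes, at 27.0 to 45.4, 29.1 to 45.5 and 18.4 to 25.1 CPM. Kdm5d, Eif2s3y and Uty rose in the E12 knockout (0.56, 0.64 and 0.42), and in the E47 knockout Kdm5d (-0.30) and Uty (-0.29) fell and Eif2s3y rose (0.25). Xist, the transcript of the inactive X chromosome, was at 7.31 and 7.73 CPM in the E47 wild-type libraries, and had 1, 2 and 1 counts over the E12 wild type, E12 knockout and E47 knockout. The 3 E47 calls ended without the second E47 knockout library, at -0.21 for Kdm5d, 0.22 for Eif2s3y and -0.14 for Uty, and without the second E47 wild-type library, at -0.20, 0.28 and -0.22. With DESeq2 the E47 calls of Eif2s3y (0.24, adjusted p = 0.087) and Uty (-0.30, adjusted p = 0.088) ended. The Eif2s3y call ended also without the first E47 wild-type library (0.23), and the E12 call of Uty without the second E12 knockout library (0.34, adjusted p = 0.050).

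The difference between the changes in E12 and in E47 was tested gene by gene. It was higher in E12 for 3208 genes and lower for 3593. The receptor gene S1pr5 (chromosome 9, 21242912 to 21248443) was at 96.0 ± 1.02 CPM in the E12 wild type and 1.83 ± 0.628 CPM in the E12 knockout. In the E47 lines it was at 0.427 ± 0.107 CPM in the wild type and 11.8 ± 0.0978 CPM in the knockout (difference of changes -10.52, SE 0.246, adjusted p = 2.2e-13). Pcdhga11 differed by 10.26 the other way, with the overlap given before. The wild types themselves differed more in S1pr5 (96.0 and 0.427 CPM) than the knockouts did (1.83 and 11.8 CPM). Cpxm2, Nkx2-1, Mal2 and Ripk4 were lower in the E12 knockout and higher in the E47 knockout, at 8.64 ± 1.12, 3.87 ± 0.106, 7.54 ± 1.77 and 7.34 ± 0.729 CPM in the latter and at 6 counts or fewer in the E12 knockout. Adcy4, Tal1, Sox7 and Inpp5d were at 29.3 ± 0.699, 43.7 ± 0.213, 7.96 ± 0.104 and 16.6 ± 1.41 CPM in the E47 wild type and at 6 counts or fewer in every other group. Among the regulators, Id1 differed by -0.99, Id3 by -0.63, Tcf4 by 1.54, Cdkn1a by -0.91 and Cdkn2b by -1.68. The Sox7 difference was not past the test without the second E12 knockout library (adjusted p = 1.0).

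Camera called 13 lists for this difference, and none with an estimated correlation. Higher in E12 than in E47 were the changes of contractile genes (15 higher, 5 lower, adjusted p = 0.0096, 0.31 with an estimated correlation), G1/S genes (17 and 2, 0.031, 0.69), G2/M genes (34 and 4, 0.00010, 0.43), histones (8 and 0, 0.0096, 0.31), sex-specific transcripts (4 and 0, 0.025, 0.36) and endothelial markers (10 and 0, 1.5e-06, 0.16). Lower in E12 were those of modulated smooth muscle genes (4 and 13, 0.014, 0.35), cytokines (3 and 16, 0.00076, 0.21), Wnt pathway genes (2 and 14, 0.011, 0.24), immediate early genes (2 and 12, 0.015, 0.66), nuclear genes of oxidative phosphorylation (0 and 18, 0.0096, 0.69), adventitial fibroblast markers (2 and 8, 0.045, 0.31) and mesothelial markers (1 and 6, 0.0021, 0.21). Adjusted over the list alone, 16 contractile genes, 5 sex-specific transcripts and 11 endothelial markers were higher, 1 nuclear gene of oxidative phosphorylation was higher and 9 adventitial markers were lower. Myh11 differed by 2.19, Mki67 by 1.65, Ptgs2 by -3.77 and Thbs2 by -7.65. The G1/S call ended without the second E12 knockout library (adjusted p = 0.12) or the first E12 wild-type library (0.052), and the adventitial call without the first E12 knockout library (0.053), the first E47 knockout library (0.067) or the second E47 wild-type library (0.055). The p53 target list was called without the second E47 knockout library (0.041).

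The wild types were compared to see how far these cell populations differed with no knockout between them. Mesothelial markers were higher in the E12 wild type, and endothelial and contractile genes in the E47 wild type, but these list calls did not hold with an estimated correlation (adjusted p = 0.12 for each). Msln was at 205 ± 12.3 CPM in the E12 wild type and 1.09 ± 0.118 CPM in the E47 wild type (log2 difference 7.52, SE 0.123, adjusted p = 2.1e-15), and Tnfsf18 at 839 ± 7.23 and 3.02 ± 0.903 CPM (8.19, SE 0.138). Thy1, a surface marker of fibroblasts and other cells, was at 0.512 ± 0.089 and 296 ± 10.4 CPM (-9.14, SE 0.14), and Postn, periostin, at 0.971 ± 0.108 and 298 ± 6.12 CPM (-8.26, SE 0.128). Of 13992 genes 3890 were higher and 3855 lower in the E12 wild type, and 1180 and 1317 by more than 2-fold. Mmp3 differed by 7.91. Wt1 and Tmem108 had no count in the E47 wild type and were at least 153-fold and 145-fold higher in the E12 wild type. Irx2, Isl1, Lama1 and Clec1a had no count in the E12 wild type and were at least 79.7-fold, 66.3-fold, 59.9-fold and 37.9-fold higher in the E47 wild type.

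Camera called 16 lists between the wild types, and none with an estimated correlation. Higher in the E12 wild type were G1/S genes (27 higher, 2 lower, adjusted p = 0.00029, 0.47 with an estimated correlation), G2/M genes (37 and 4, 2.5e-05, 0.40), cytokines (12 and 5, 0.029, 0.27), cholesterol synthesis genes (15 and 1, 0.0074, 0.48), nuclear genes of oxidative phosphorylation (23 and 0, 0.00029, 0.49) and mesothelial markers (7 and 1, 7.2e-05, 0.12). Lower were contractile genes (3 and 19, 1.4e-05, 0.12), matrix structural genes (4 and 22, 3.1e-05, 0.39), interferon-stimulated genes (5 and 15, 0.044, 0.49), TGF-beta and BMP pathway genes (5 and 21, 0.00066, 0.47), osteochondrogenic genes (1 and 12, 0.00025, 0.27), Hox genes (2 and 15, 0.00073, 0.39), mitochondrially encoded mRNAs (0 and 10, 0.011, 0.62), histones (0 and 16, 1.8e-05, 0.12), endothelial markers (1 and 11, 4.6e-06, 0.12) and pericyte markers (2 and 6, 0.023, 0.27). Adjusted over the list alone, 39 G2/M genes, 13 cytokines and 6 interferon-stimulated genes were higher, and 23 matrix structural genes, 18 Hox genes and 17 histones were lower. Sfrp2 was at 177 ± 2.42 CPM in the E12 wild type and 2577 ± 195 CPM in the E47 wild type, and Vcam1 at 2147 and 143 CPM.

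Calls shared by both knockouts were compared with the overlap of independent lists. Genes that rose in both included Bche (5.54 in E12, and from 3 counts to 6.96 ± 0.0934 CPM in E47), Il33 (4.03 and 7.47), Gatm (4.47 and 3.23), the iron exporter gene Slc40a1 (3.50 and 3.36), Foxf2 (3.19 and 3.67), Opcml (3.24 and 4.16) and Krt14 (5.58 and 3.08). Xlr3b also rose in both, with the reservation given before, and Steap4 and Tmem215 were at 6.10 ± 1.14 and 7.52 ± 0.773 CPM in the E12 knockout and at 2.24 ± 0.515 and 0.494 ± 0.0367 CPM in the E47 knockout, with 1 count each in the E47 wild type. Bmp6 fell in both (-3.81 and -4.71), as did Hoxa9 (-5.24 and -4.78) and Plekhg1 (-5.16 and -3.86). Car8, Mycn, Kctd12b, Hoxd8, Rgs16 and Klf12 fell to 3 counts or fewer in the E12 knockout from 0.133 to 2.02 CPM, and in the E47 lines were at 7.75 to 37.5 CPM in the wild type and at 1.87 CPM or lower in the knockout. The rule took shared genes by their mean CPM over all 8 libraries, to which the E47 wild type gave most here. The lowest E12 wild-type level lay under the limit for 1 library of that group (0.192 and 0.216 CPM), so the E12 falls can rest on few counts. Of these E12 calls, that of Hoxd8 ended with DESeq2 (adjusted p = 0.052) and without either knockout library (0.14 and 0.11), the first E12 wild-type library (0.20) or either E47 wild-type library (0.054 and 0.058), that of Rgs16 without either knockout library (0.097 and 0.072) or the second wild-type library (0.081), and that of Kctd12b without the second wild-type library (0.081).

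In all, 1050 genes rose in both knockouts against 849 for independent lists (odds ratio 1.495, Fisher's exact test, two-sided, adjusted p = 2.6e-19), and 1207 fell in both against 943 (odds ratio 1.63, adjusted p = 1.5e-29). Genes that rose in E12 and fell in E47 numbered 740 against 844 (odds ratio 0.799, adjusted p = 1.7e-06), and those that fell in E12 and rose in E47 numbered 1108 against 949 (odds ratio 1.35, adjusted p = 6.7e-12). P-values were adjusted over these 4 tests, and genes are not independent replicates. Of 4105 genes called in both, 55.0% moved the same way. The changes correlated at r = 0.0694 and rho = 0.0784 across the 13992 genes. The comparisons had separate control libraries. With the wild types exchanged between the knockouts, a setting chosen after seeing the data, 641 genes were higher in both, 787 lower in both and 2516 moved in opposite directions, against 1848 with the matched wild types.

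With the libraries of each genotype summed to 1 profile, both knockouts were compared with both wild types. Foxf2 and Gatm, which rose in each knockout, had the smallest p-values, with log2 changes of 3.42 (SE 0.446) and 3.95 (SE 0.529) and adjusted p = 0.998 for each. edgeR called 0 of 14704 genes higher and 0 lower, with 391 (2.66%) at an unadjusted p under 0.05, while DESeq2 called 16 higher and 30 lower.

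Whole chromosomes differed in their median change. In the E12 knockout, genes of chromosome 18 were higher by a median of 0.55 (bootstrap SE 0.0210), with 84.0% of 375 genes above the median of all genes, and genes of chromosome 9 were lower, at -0.35 (SE 0.0165), with 17.6% of 771 genes above it. Chromosome 1 was at 0.31, chromosome 19 at -0.17 and chromosome 15 at -0.14. In the E47 knockout, chromosome 19 was at 0.29 (SE 0.0256), chromosome 16 at -0.29 and chromosome 11 at 0.26. Chromosome 10, which carries Tcf3, was at -0.08 and -0.07. In 1000 random assignments of genes to chromosomes, the largest of the autosome medians stayed under 0.0657 in E12 and 0.0754 in E47 in 95% of cases. Tcf4, Egr1, Pcdhga11 and Pcdhga4, named before, lie on chromosome 18, and Cdkn2d, Smad6 and Cnn1 lie on chromosome 9. The changes given for these and all other single genes include the shift of their chromosome, which matters most for small changes. With chromosome medians removed, a setting chosen after seeing the data, 2697 genes rose and 3181 fell in the E12 knockout and 3600 rose and 3681 fell in the E47 knockout.

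**Figure D5:**
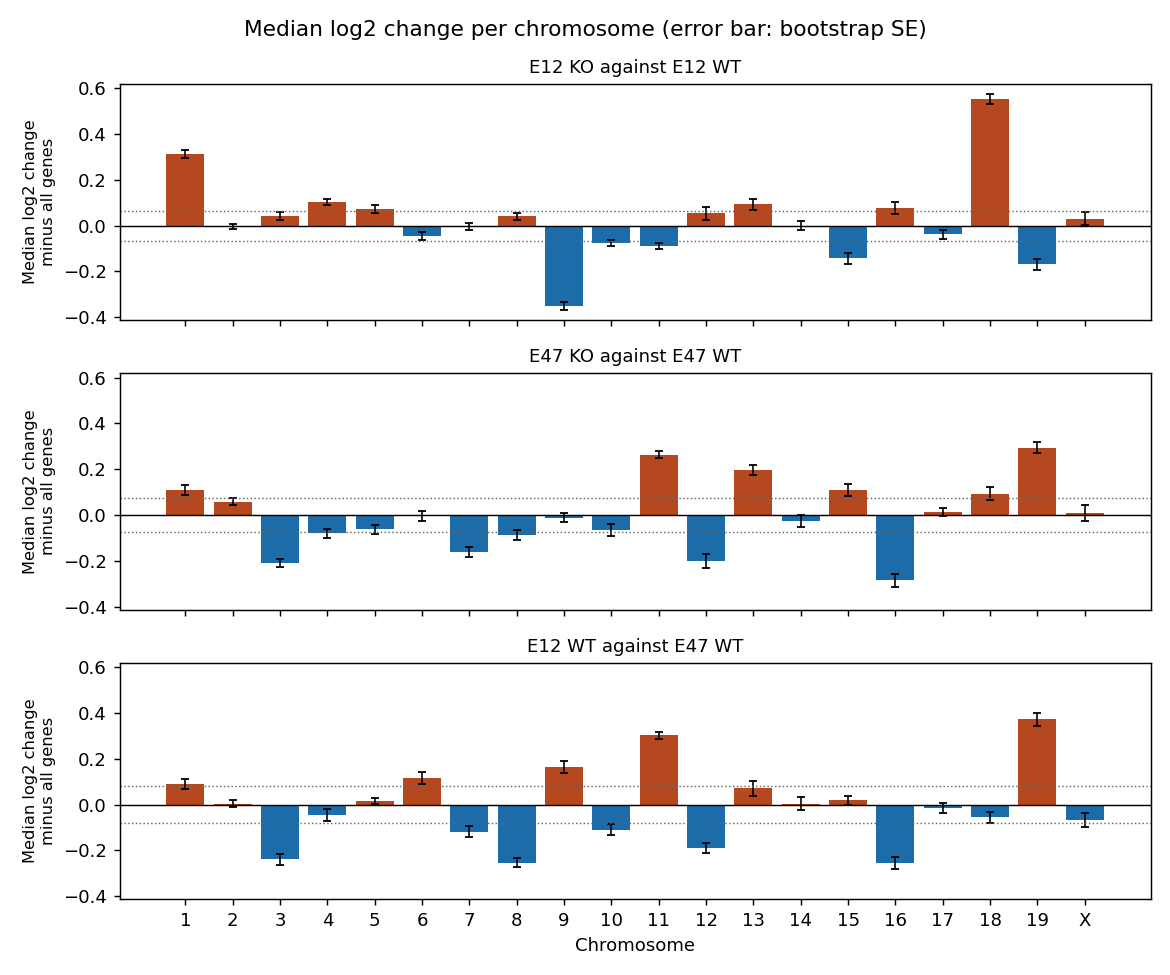
Median log2 change of the tested genes of each chromosome minus the median of all genes, for the E12 knockout, the E47 knockout and the wild types against each other, with bootstrap SE, where dotted lines mark the value that the largest autosome median exceeded in 5% of 1000 random assignments. Chromosome 18 stood at 0.55 in the E12 knockout and chromosome 19 at 0.37 between the wild types.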

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

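The tests of Kdr, of the endothelial list and of the contractile genes below were chosen after their results had been seen, and those of Tcf3 before. The contrast of E12 with E47 was tested gene by gene as the difference between the knockout changes. That difference was higher in E12 for 3208 genes and lower for 3593. Of the genes that the rule took for the size of the difference or always named, and of the lists, those with a difference past the test are given here as E12 change minus E47 change on the log2 scale.

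Of the genes chosen for the size of the difference, those with over 3 counts in every group were S1pr5 at -10.52 and Pcdhga11 at 10.26, and the exons of Pcdhga11 overlap its neighbours. Of the E and Id protein genes, Tcf4 differed by 1.54, Id1 by -0.99 and Id3 by -0.63. Of the CDK inhibitors, Cdkn1a differed by -0.91, Cdkn1b by 0.40, Cdkn2a by -0.90, Cdkn2b by -1.68, Cdkn2c by 0.59 and Cdkn2d by -0.85. Contractile genes differed by 0.50 for Acta2, 2.19 for Myh11 and 0.71 for Cnn1. The Y-linked genes differed by 0.86 for Kdm5d, 0.39 for Eif2s3y and 0.71 for Uty.

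Lists differed in the same way, given as the median difference with group totals under 3 counts set to 3. It was 0.56 for contractile genes, -1.07 for modulated smooth muscle genes, 0.28 for G1/S genes, 0.43 for G2/M genes, -1.85 for cytokines, -1.68 for Wnt pathway genes, -0.66 for immediate early genes, -0.45 for nuclear genes of oxidative phosphorylation, 0.70 for sex-specific transcripts, 0.89 for histones, 5.86 for endothelial markers, -1.46 for adventitial markers and -4.33 for mesothelial markers. None of these 13 calls held with an estimated correlation. Each wild type serves 1 of the changes, so a difference between the wild types enters every one of these values with the opposite sign.

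Endothelial markers were abundant in the E47 wild type alone, with Pecam1 at 203, Mmrn2 at 189, Emcn at 177 and Cdh5 at 170.5 CPM. The markers are 12 tested genes, of which 0 stood on another list and 3 were at 1 CPM or more in both E12 wild-type libraries. The list was lower in the E12 wild type than in the E47 wild type by a median of -6.44. A low level was thus also found in cells without the E47 knockout, which does not show why the E47 knockout was low. Endothelial cells among the E47 wild-type cells stay open as the source of these transcripts. All 12 members were lower in the E47 knockout, but these are the genes that raised the question, so their fall is no test of it. Kdr, an endothelial receptor gene, was among the 12, yet it was higher in the E12 wild type than in the E47 wild type by 0.73 (SE 0.291). That is 1 gene at a low level, so endothelial cells that express Kdr stay open too. Tek, another endothelial receptor gene, chosen after its values were seen, was at 1.08 and 1.68 CPM in the E47 wild-type libraries. Without its levels in the other groups, that low level of Tek decides nothing. For the contractile genes, endothelial cells stay open as well, because the test cannot decide. It assumed that endothelial cells lack contractile transcripts, which was not measured here, and its bound was reworded with the values known. The whole contractile list was lower in the E47 knockout than in the E47 wild type by a median of -0.80 (bootstrap SE 0.203), with 19 of 26 members lower and 2 higher. Xist, given before, was likewise counted almost only in the E47 wild type, beside Y-linked genes, and its source was not tested. A candidate explanation that stays open is that the populations differed in cell type or mixture, be it the E47 wild type, the others or both. Mesothelial markers were higher in the E12 wild type and in the E47 knockout than in the E47 wild type. Their medians were 5.22 and 3.12, with 1 and 2 of 8 members going the other way. An effect of E47 itself stays open too, since each genotype was 1 population as far as the labels tell.

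The Tcf3 count was higher in both knockouts, where a loss of 1 isoform was the label. Scaling of the libraries is argued against, because the smallest log2 change of Tcf3 over 3 scalings and both comparisons was 0.41 (SE 0.0634). Differences between populations cannot be told apart from an effect of the knockouts. The wild types differed in Tcf3 by 0.20, less than either knockout change. The bound set for this test was wrong, because 46.3% of tested genes differed between the wild types by at least the smaller Tcf3 change, so a small difference in 1 gene excludes nothing. More transcript from the remaining isoform or from the targeted allele may also raise the count and stays open, because the 2 mutually exclusive exons are not separated by a count per gene.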

How the results depend on the processing

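The settings that exchange control libraries, leave the E47 wild type out of the fit or remove chromosome medians were chosen after seeing the data. No paired analysis was possible because replicate numbers follow only the order of the libraries. Where 1 library was left out, the lone library of its genotype was assumed to vary like the other groups. Under other settings 194 counts stayed within 1.5 times and 13 moved beyond it. None of the named genes reversed: 3623 values stayed on their side of the threshold and 64 lost their call. Among the E12 and E47 calls of all genes, 0 reversed with DESeq2, RLE size factors, other filters, a fit of the compared groups or 1 library left out, and DESeq2 kept 5251 of 6490 in E12 and 6379 of 7728 in E47. Without the second E47 wild-type library 5728 of 7728 E47 calls were kept.

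Leaving out 1 library in turn gave 2463 to 3075 higher and 2824 to 3371 lower genes in E12, 2921 to 4079 and 2946 to 4088 in E47, 2606 to 3268 and 3111 to 3636 for the difference, and 3039 to 3973 and 3100 to 3822 between the wild types. Shared calls were 811 to 995 higher in both, 952 to 1262 lower in both and 1344 to 1979 opposite. With the wild types exchanged between the knockouts, 641 were higher in both, 787 lower in both and 2516 opposite. The cause was not tested.

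In the fit of summed profiles, edgeR called 0 genes in either direction, with 391 at an unadjusted p under 0.05, and 0 to 0 without any 1 profile. DESeq2 called 16 higher and 30 lower, and edgeR without the filter beyond 1 count called 4 higher and 1 lower. The cause was not tested.

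Calls of lists depended most on the test. In E12, E47 and the difference camera called 5, 15 and 13 lists, 0, 0 and 0 with an estimated correlation, and fry 21, 26 and 25. Fry does not compare a list with other genes. A higher correlation does not account for every call lost with an estimated correlation. For endothelial markers in E47 the estimate was 0.0045, below the preset 0.01. Their unadjusted camera p still went from 1.5e-09 to 0.0034. For mitochondrially encoded mRNAs the estimate was far above the preset, at 0.746. The cause of the lost calls was not tested further, so they do not show that correlation between genes made the calls. Leaving out 1 library gave 5 to 8 lists in E12, with 8 without the second E12 knockout library, 15 to 16 in E47 and 12 to 14 for the difference. The Wnt list in E47 reversed with fry, to -3.09 as signed log10 p, and the cause was not tested. Over the list tests of E12, E47 and the difference, 1005 stayed, 45 gained a call and 38 lost it. Depth limits the genes with few counts, for which levels or lower bounds are given.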

Other observations

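The tests of chromosomes and of genes near Tcf3 were chosen before their results were seen. Mesothelial keratins did not move as a group. Krt18 was at 117 ± 7.86 CPM in the E47 wild type and at 0.534 ± 0.303, 2.45 ± 0.112 and 1.18 ± 0.126 CPM in the E12 wild type, E12 knockout and E47 knockout. Krt19 was lowest in the E47 wild type, at 13.0 ± 0.91 CPM, against 387 ± 32.2, 171 ± 10.4 and 152 ± 5.73 CPM. Upk1b followed Krt19, at 409, 187, 9.11 and 60.2 CPM in the E12 wild type, E12 knockout, E47 wild type and E47 knockout.

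Whole chromosomes shifted in expression, which a gain or loss of a chromosome in most cells may produce. In the E12 knockout the autosome farthest from the median of all genes was chromosome 18, at 0.55, close to the 0.58 that 3 copies against 2 would give. Its libraries lay at 0.36 and 0.36 in the knockout and at -0.19 and -0.17 in the wild type. GC content and length of the transcripts are argued against, since 0.51 was left after their trend was removed. A cluster of genes in part of the chromosome is argued against too, since the smallest of 3 equal parts had a median of 0.54. A gain of chromosome 18 in the E12 knockout cells is a hypothesis, but 2 other autosomes also passed the bound of 0.3 set for the test. Chromosome 9 was at -0.35, with -0.36, -0.32 and -0.37 in its 3 parts, and chromosome 1 at 0.31, with 0.37, 0.28 and 0.32. Neither is the 0.58 of 3 copies against 2 or the -1 of 1 against 2. Chromosome 1 lay within 1 SE (0.0195) of the 0.32 of 5 copies against 4, and the size of the shift of chromosome 9 lay between that and the 0.42 of 4 against 3. How many copies the cells had, and a change in a share of the cells, were not tested. Between the wild types, chromosome 19 was at 0.37, with 0.33 after the GC and length trend and 0.33 in the smallest part. That too was below 0.58, and lay between 0.32 and 0.42. Chromosome 11 was also past the bound there, at 0.30, with 0.24, 0.32 and 0.36 in its parts, so a gain or loss between the wild types is a hypothesis only. In the E47 knockout, chromosome 19 was at 0.29, with 0.26 after the trend and 0.26 in the smallest part. That median lay between the bounds set for the test, so a copy change cannot be told apart there from a change of expression. Chromosome 19 was also taken per library, relative to the mean of the libraries. It lay at -0.21 and -0.22 in the E47 wild type and at 0.06 and 0.07 in the E47 knockout. The E12 wild type lay at 0.16 and 0.16 and the E12 knockout at -0.03 and -0.02. The low E47 wild type thus enters both this shift and the one between the wild types. Chromosome 11 was also lowest in the E47 wild type, at -0.18 and -0.20. No DNA was measured, and copy number was not tested directly.

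DNA carried over beside the targeted locus might give more calls near Tcf3. Of 184 tested genes within 5 Mb of Tcf3, 73 were called in E12 (39.7%, against 46.6% of the others), an odds ratio of 0.753 (95% interval 0.551 to 1.02, Fisher's exact test, two-sided, p = 0.063). In E47 99 were called (53.8%, against 55.3%), an odds ratio of 0.941 (0.696 to 1.28, Fisher's exact test, two-sided, p = 0.71). Both upper limits lay under the bound of 1.5 set for the test, so these values argue against an excess of calls near the locus.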
